A study of Mus musculus with 24 samples.

How the data were processed

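Subcutaneous fat of the 4th mammary gland of C57BL/6 mice was flash frozen, and total RNA was treated with DNase, depleted of ribosomal RNA and sequenced. The 24 samples formed 6 groups of 4 by diet (Chow or HFD) and position (no tumor, contralateral, peritumoral), taken from the sample labels. The values analysed were the counts per gene deposited by the authors as a single matrix of 39017 genes by 24 libraries on mm10. The authors' notes name TopHat for alignment and DESeq for testing, with versions not given in the sources used here. The strand used for counting is not given in the sources used here, so genes that overlap on opposite strands, and near-identical copies such as the hemoglobin genes, have uncertain separate counts. Of the 39017 genes, 37607 had a symbol, 1410 had none and 6 symbols were repeated. Gene positions and exon bases were those of the deposited matrix, and GC content was that of the longest GENCODE transcript.

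Each comparison of 2 groups was fitted on its own 8 libraries, and each of the 2 interactions on 16, with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood F test, TMM factors). Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The 9 comparisons were HFD against Chow at each of 3 positions, peritumoral against contralateral fat on each diet, contralateral against no-tumor fat on each diet, and the interactions of diet with tumor side and with tumor bearing. Printed CPM were scaled with TMM over all 24 libraries. The matrix was read with data.table, version 1.17.8.

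Gene lists were tested with camera of limma 3.58.1 (preset correlation between genes 0.01, prior count 2), and p-values were adjusted over the lists of a comparison, where at least 3 members were measured. The 28 lists covered creatine metabolism, mature adipocyte, adipose expansion, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, thermogenic fat, oxidative phosphorylation, insulin response, macrophage, lipid-associated macrophage, T and NK cell, B cell, lymph node stroma and high endothelium, neutrophil, mast cell, interferon response, cytokine and chemokine, extracellular matrix, stromal progenitor and fibroblast, endothelial, cell cycle, hypoxia and glycolysis, mammary epithelium, skeletal muscle, red blood cell, immediate early and tissue handling, and mitochondrial genome genes. Of the B cell list 15 of 16 genes were in the table. The adipose expansion list shares 4 of its 9 genes with the lipid-associated macrophage and the cytokine and chemokine lists. Results of these 3 lists are therefore not independent. Clock genes (a Dbp group and an Arntl group) and myelin genes were added after the data were seen. The preset correlation can understate how far the genes of a list move together. Lists that passed are therefore reported with their adjusted p at an estimated correlation as well.

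The genes named in the text followed a fixed rule. It took the creatine list, up to 8 higher and 8 lower genes per comparison with the lowest adjusted p, an absolute log2 fold change of at least 1, a mean of at least 5 CPM in the higher group and no overlap of replicates (overlap was allowed for interactions). Placeholder symbols were left out. It also took up to 4 members of each list that passed, and up to 2 of each list that did not. Lep, Mki67, Glycam1, Ms4a1, Acta1, Malat1 and Neat1 served as measures per library. Single values per library were compared by exact permutation of the labels, whose smallest two-sided p is 0.0286 with 4 against 4 libraries. Total counts ran from 9.13 to 18.2 M per library, so a gene such as Gatm was counted 172 times in Chow contralateral replicate 1.

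The tests were tried on simulated counts with 100 genes planted at each fold. Of the genes planted at 2-fold, edgeR recovered 73% for diet in no-tumor fat, 72% in contralateral and 60% in peritumoral fat, 70% and 71% for tumor side on Chow and HFD. It recovered 72% and 84% for tumor bearing on Chow and HFD, and 48% and 64% for the interactions with side and bearing. At 1.5-fold it recovered 47%, 47%, 16%, 28%, 29%, 48%, 54%, 7% and 26% in the same order, with 1 to 11 false calls, against 13 to 33 with DESeq2. A planted list was found in the right direction in all 9 comparisons, with 0 or 1 other lists called. Genes were simulated independently of each other, so this does not show how often the list test errs where the genes of a list move together.

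Alternatives chosen before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 1 CPM in at least 4 libraries, all 24 libraries in 1 fit, and limma voom with sample quality weights. The others were the replicate number as a block, the B cell mean as a covariate and leaving out each library. For lists they were an estimated correlation, fry, the block and leaving out each library, and for correlations across genes a minimum mean of 5 CPM. A skeletal muscle covariate, offsets for gene length and GC content (natural spline with 4 degrees of freedom; 98.8% of tested genes had a GC value) and leaving out libraries with Glycam1 at 5 CPM or more were added after the data were seen. No per-sample column of the table was left unused (0). Raw reads were not analysed here, and some genes are not reported here.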

Results

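Subcutaneous fat of the 4th mammary gland was taken from C57BL/6 mice fed Chow or a diet labelled HFD, and its total RNA was sequenced after depletion of ribosomal RNA. The series describes the animals as lean and obese, and asks how fat close to a breast tumor differs from fat far from it. The 24 libraries formed 6 groups of 4, by diet and by position: fat labelled as having no tumor (no-tumor fat), fat of the opposite side (contralateral fat) and fat next to the tumor (peritumoral fat). Total counts per library ran from 9.13 to 18.2 M. They lay between 16.12 and 16.64 M in Chow no-tumor, 11.69 and 13.85 M in Chow contralateral, and 9.13 and 14.46 M in Chow peritumoral libraries. On HFD they lay between 14.98 and 16.53 M in no-tumor, 16.67 and 17.29 M in contralateral, and 15.98 and 18.2 M in peritumoral libraries. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Throughout, fold changes are log2 ± SE with edgeR's quasi-likelihood test and Benjamini-Hochberg adjusted p, and levels are counts scaled to library size (CPM), as mean ± SD with n = 4 libraries per group. Gene lists were tested with camera at a preset correlation between genes, and the estimated-correlation p of a list is its adjusted p with that correlation estimated from the data.

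The HFD peritumoral libraries stood apart from the others. The first principal component held 38.4% of the variance, and the 4 HFD peritumoral libraries lay between 48.1 and 85.62 on it, with every other library at 33.25 or below. The second component held 20%. Chow contralateral replicate 1 marked the low end of the first component at -54.63. The chi-square between replicates, averaged over genes, ran from 3.74 to 157.1 over 36 pairs, so no pair matched within sampling noise on that measure. Single genes can weigh heavily in such a mean. The values of 157.1, 140.4 and 126 involved Chow contralateral replicate 2, where Gm42418 took 11.367% of counts. That gene took 0.021% to 0.9% in the rest of the group, so the mean does not describe typical genes.

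**Figure D1:**
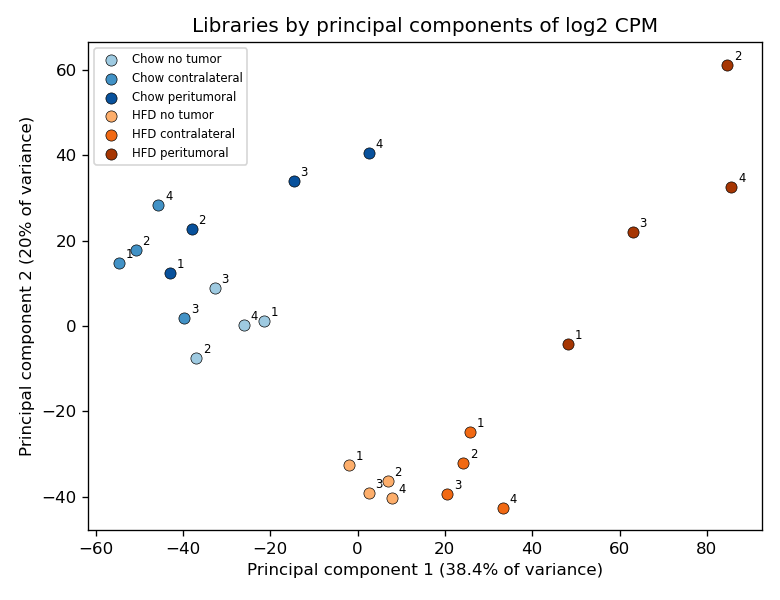
Each point is 1 library placed by the first (38.4% of variance) and second (20% of variance) principal component of log2 CPM, colored by group and numbered by replicate. The 4 HFD peritumoral libraries sit at 48.1 or more on the first component, to the right of all other libraries.

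Nuclear and mitochondrial RNA were compared between groups as well. Malat1, an abundant nuclear noncoding RNA, stood at 10840 ± 250 CPM in Chow contralateral, 10760 ± 744 in Chow peritumoral and 8420 ± 463 in Chow no-tumor fat. On HFD it stood at 5438 ± 134, 4972 ± 404 and 7009 ± 540 in the same order (SD, n = 4). In each of the 3 diet comparisons its 4 HFD libraries lay below the 4 Chow libraries (two-sided exact permutation p = 0.0286, the smallest this design can give, adjusted p = 0.04 over the 7 comparisons). Neat1, another nuclear noncoding RNA, was lower on HFD in contralateral (416.1 ± 54.5 against 904 ± 156 CPM) and peritumoral fat (362.2 ± 49.6 against 758.9 ± 180 CPM). In no-tumor fat it was higher on HFD, at 544.6 ± 45.6 against 411.1 ± 34 CPM (exact permutation p = 0.0286 and adjusted p = 0.05 in each). The mitochondrial ribosomal RNA share of counts was 32.42% ± 2.38 in Chow no-tumor, 24.87% ± 1.4 in Chow contralateral and 29.44% ± 5.39 in Chow peritumoral fat, against 21.61% ± 0.713, 23.85% ± 0.959 and 25.99% ± 1.79 on HFD (SD, n = 4). The libraries of the 2 groups did not overlap in that share for diet in no-tumor fat, nor for contralateral against no-tumor fat on Chow or on HFD. Each of these had the smallest possible exact permutation p, 0.0286 (adjusted p = 0.0667). They missed the threshold because too few comparisons reached that smallest value, which does not show that the shares were alike.

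Creatine synthesis genes come first, since the series concerns creatine exchanged between fat cells and breast cancer cells. Gatm (ENSMUSG00000027199; mm10, chromosome 2, 122594467 to 122611303, minus strand, 3001 exon bases) encodes the enzyme of the first step of creatine synthesis. On HFD it was higher in peritumoral than in contralateral fat by 1.80 ± 0.30, at 28.2 ± 12.2 against 8.02 ± 0.81 CPM (adjusted p = 0.00419). All 4 peritumoral libraries, at 12.5, 38.0, 24.8 and 37.7 CPM, lay above all 4 contralateral ones. On Chow the same contrast was 0.23 ± 0.16, at 12.1 ± 2.01 against 10.4 ± 1.91 CPM (adjusted p = 0.644). The difference between these 2 effects, 1.60 ± 0.38, did not pass with edgeR (adjusted p = 0.0907). It passed with DESeq2 (1.57), with all 24 libraries in 1 fit (1.60) and without HFD peritumoral replicate 1 (1.85). That replicate had the lowest Gatm of its group, so leaving it out raises the difference. On simulated counts of this interaction 21 of 100 DESeq2 calls were false, and 4 of 59 with edgeR.

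HFD raised Gatm in peritumoral fat by 1.14 ± 0.31 (adjusted p = 0.021), gave a lower value in contralateral fat (-0.41 ± 0.14, adjusted p = 0.0262) and gave 0.01 ± 0.16 in no-tumor fat (adjusted p = 0.985). The peritumoral call was lost without Chow peritumoral replicate 1 (1.04, adjusted p = 0.0654) or 2 (1.13, adjusted p = 0.0521) and without HFD peritumoral replicate 2 (0.96) or 4 (0.98). The contralateral call was lost with all 24 libraries in 1 fit (-0.37) and without Chow contralateral replicate 1 (-0.35, adjusted p = 0.0768) or 2 (-0.29, adjusted p = 0.107) or HFD contralateral replicate 3 (-0.36) or 4 (-0.38).

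Gamt (ENSMUSG00000020150; chromosome 10, 80258151 to 80261012, minus strand), which encodes the enzyme of the final step of creatine synthesis, rose on HFD at all 3 positions. It rose by 0.86 ± 0.20 in no-tumor fat (12.9 ± 1.84 against 6.97 ± 2.36 CPM, adjusted p = 0.0108). The rise was 1.07 ± 0.14 in contralateral fat (10.7 ± 0.635 against 5 ± 1.08 CPM, adjusted p = 0.000112) and 0.78 ± 0.19 in peritumoral fat (8.96 ± 1.4 against 4.91 ± 0.876 CPM, adjusted p = 0.0109). Peritumoral and contralateral fat gave Gamt differences of 0.00 ± 0.20 on Chow and -0.27 ± 0.13 on HFD, neither of which passed. The creatine transporter gene Slc6a8 (ENSMUSG00000019558; chromosome X, 73673150 to 73682502) lay between 22.7 ± 1.93 and 31.9 ± 7.58 CPM over the 6 groups and passed in no comparison.

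Among the creatine kinase genes, Ckmt1 (ENSMUSG00000000308; chromosome 2, 121357714 to 121363737), a mitochondrial form, fell by 1.29 ± 0.32 on HFD in contralateral fat (1.14 ± 0.534 against 2.71 ± 0.571 CPM, adjusted p = 0.00656). Cytoplasmic Ckb (ENSMUSG00000001270; chromosome 12, 111669355 to 111672338) rose there by 0.36 ± 0.10 (18.7 ± 0.881 against 14.2 ± 2.17 CPM, adjusted p = 0.0132). Ckm (ENSMUSG00000030399; chromosome 7, 19411094 to 19421583), the muscle form, stood at 210, 129, 0.749 and 88.8 CPM in the 4 Chow contralateral libraries, a group that also held the muscle gene Ttn at 1660 ± 1180 CPM. Muscle Ckmt2 (ENSMUSG00000021622; chromosome 13, 91853387 to 91876885) averaged 1.31 ± 0.825 CPM in those libraries and 0.139 ± 0.0599 in HFD contralateral fat, and its contrasts did not pass where it was tested. As a list of 5 measured genes, creatine metabolism did not pass between peritumoral and contralateral fat on HFD (median -0.13, mean 0.32, camera adjusted p = 0.69), with Gatm its only called member.

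**Figure D2:**
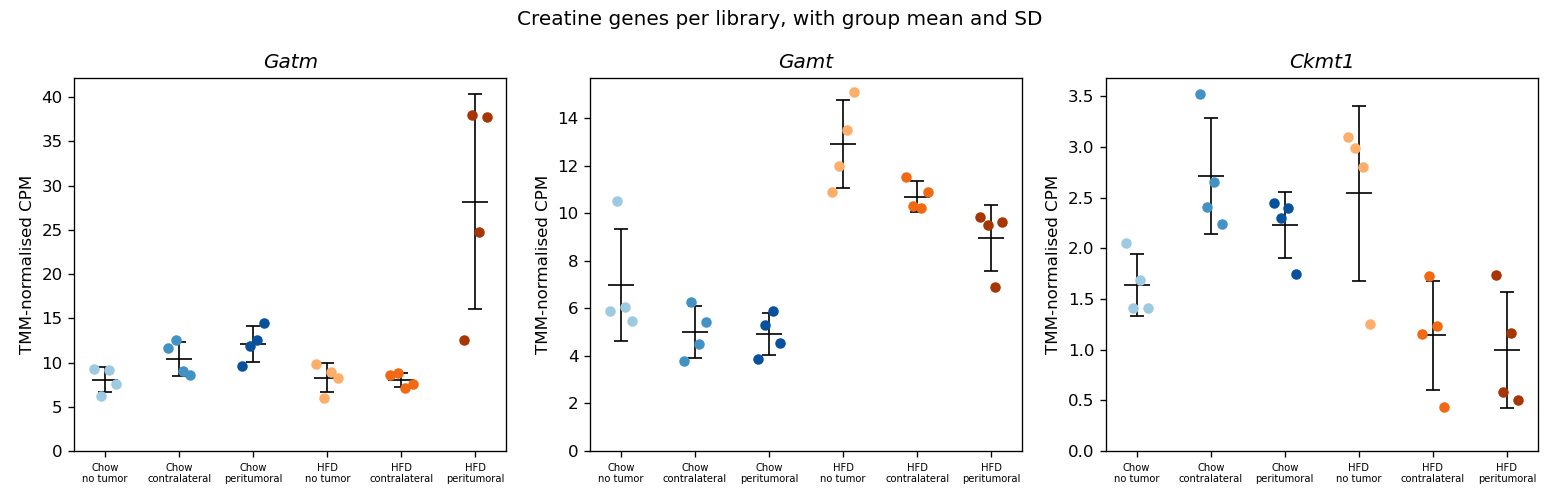
CPM of Gatm, Gamt and Ckmt1 in every library of the 6 groups, with the group mean as a line and the SD as an error bar (n = 4). Gatm lies between 12.5 and 38.0 CPM in HFD peritumoral libraries, against a mean of 8.02 in HFD contralateral libraries.

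HFD against Chow in no-tumor fat asks how the diets differed without a tumor. Markers of fat expansion and blood vessel lining were higher on HFD, and some fatty acid synthesis, interferon and mammary epithelial genes were lower. Lep (ENSMUSG00000059201; chromosome 6, 29060220 to 29073877), which encodes the satiety hormone leptin, rose by 2.77 ± 0.18, to 1870 ± 297 from 268 ± 65.2 CPM (adjusted p = 1.2e-05). Npr3, the clearance receptor of natriuretic peptides, rose by 2.17 ± 0.13, to 1840 ± 79.4 from 400 ± 80.4 CPM (adjusted p = 1.12e-06). In the adipose expansion list, 8 of 9 members rose and 0 fell, also when adjusted over the list alone (median 2.21, camera adjusted p = 1.6e-08, estimated-correlation p = 0.15). Of its 9 members 4 also belong to the lipid-associated macrophage or the cytokine and chemokine list, so the list is not specific to fat cells. Of 14 endothelial markers, 12 rose and 0 fell (12 and 1 when adjusted over the list alone). Cdh5 (ENSMUSG00000031871), a junction protein of endothelium, rose by 1.09 ± 0.06 (248 ± 3.72 against 114 ± 7.88 CPM, adjusted p = 3.39e-07). This list passed with an estimated correlation too (adjusted p = 0.03; median 0.77, camera adjusted p = 2.4e-09).

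Among the other gene groups in no-tumor fat, 10 of 22 cell cycle genes rose and 0 fell (13 and 1 when adjusted over the list alone). Cdk1, a kinase of mitotic entry, rose by 1.61 ± 0.23 at 3.38 ± 0.687 CPM (list median 0.70, camera adjusted p = 0.00029, estimated-correlation p = 0.66). Of 15 lipid-associated macrophage genes, 8 rose and 1 fell (10 and 2 when adjusted over the list alone). Mmp12, a macrophage elastase, stood at 18.5 ± 5.58 against 1.28 ± 0.225 CPM (3.82 ± 0.27, adjusted p = 8.06e-06, estimated-correlation p = 0.15). Fatty acid synthesis had 6 of 20 members lower and 0 higher (the same counts over the list alone). Among them were Mlxipl, a carbohydrate-sensing transcription factor (-0.86 ± 0.08, adjusted p = 1.01e-05), and Srebf1 (-0.67 ± 0.13, adjusted p = 0.00497, estimated-correlation p = 0.84). The mean log2 CPM of the fatty acid synthesis list was 7.605, 8.973, 7.652 and 7.117 in Chow no-tumor replicates 1 to 4. On HFD it lay between 6.917 and 7.211, so Chow replicate 2 weighed heavily and Chow replicate 4 lay within the HFD range. Cholesterol synthesis genes went both ways, with 3 higher and 6 lower of 19 (median -0.13, camera adjusted p = 0.4). Skeletal muscle genes were below 0 in 10 of 10 cases with 1 called (median -2.47, camera adjusted p = 0.25). Interferon response genes were lower in 15 of 23 cases and higher in 1 (18 and 2 over the list alone, with Usp18 at -1.12 ± 0.19, adjusted p = 0.00218, estimated-correlation p = 0.66). Chow no-tumor replicate 2 had a mean log2 CPM of 4.342 for this list, near the HFD libraries at 3.978 to 4.311. The other Chow no-tumor libraries lay between 5.133 and 5.316. All 7 measured mitochondrial genome genes fell (median -0.50; mt-Co1 -0.57 ± 0.10, adjusted p = 0.00125, estimated-correlation p = 0.66), in libraries whose mitochondrial ribosomal RNA share was 21.61% ± 0.713 against 32.42% ± 2.38 (SD). Of 28 nuclear oxidative phosphorylation genes, 8 fell with 0 rising (median -0.21, estimated-correlation p = 0.82). Chow no-tumor replicate 2 had a mean log2 CPM of 6.471 for this list, above the other Chow no-tumor libraries at 6.026 to 6.115. The HFD libraries lay between 5.888 and 6.054. Mast cell markers were lower in 4 of 6 cases (Mcpt4 -0.67 ± 0.10, adjusted p = 0.000653, estimated-correlation p = 0.66), as were mammary epithelial genes in 7 of 16 (Csn3 -0.83 ± 0.12, adjusted p = 0.000749, estimated-correlation p = 0.69). Stromal progenitor and fibroblast markers had 2 higher and 8 lower of 14, with Dpp4 at -0.70 ± 0.09 (adjusted p = 0.000116), and missed the list threshold (median -0.31, camera adjusted p = 0.05, estimated-correlation p = 0.82).

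Outside the lists, Slc6a13 (ENSMUSG00000030108), a transporter of GABA and taurine, rose by 2.53 ± 0.09 (45.9 ± 3.74 against 7.75 ± 0.853 CPM, adjusted p = 5.66e-08). The insulin-like growth factor binding protein gene Igfbp3 rose by 1.55 ± 0.07 (70.2 ± 6.05 against 23.5 ± 1.08 CPM, adjusted p = 1.26e-07). Complement gene C3 fell by 1.20 ± 0.08 (839 ± 15.7 against 1890 ± 169 CPM, adjusted p = 8.52e-07), and the adipocyte complement factor Cfd, adipsin, fell by 1.52 ± 0.10 (2230 ± 130 against 6260 ± 884 CPM, adjusted p = 1.2e-06). With edgeR 3943 of 15827 genes were called, 2160 higher and 1783 lower, of which 416 and 286 differed by more than 2-fold. Of 27 gene lists 10 passed, 1 of them with an estimated correlation.

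HFD against Chow in contralateral fat asks how the diets differed in tumor-bearing mice away from the tumor. Fat expansion genes and some adipocyte and matrix genes were higher on HFD, and most mammary epithelial and some fatty acid synthesis genes were lower. Of 27 lists 14 passed with a preset correlation and 0 with an estimated one. Of 17 mature adipocyte genes, 10 rose and 1 fell (the same counts when adjusted over the list alone). The fatty acid carrier Fabp4 (ENSMUSG00000062515) rose by 0.97 ± 0.09 to 5900 ± 394 from 2940 ± 77.8 CPM (adjusted p = 9.11e-06). The hormone gene Adipoq rose by 0.96 ± 0.09 to 2630 ± 96.8 from 1310 ± 124 CPM (adjusted p = 9.29e-06; list median 0.48, estimated-correlation p = 0.54). All 9 genes of the adipose expansion list rose (median 3.09, with Npr3 at 2.54 ± 0.17 and Bmp3 at 3.09 ± 0.17, estimated-correlation p = 0.54). These include the 4 shared with the lipid-associated macrophage and the cytokine and chemokine lists. The progesterone receptor gene Pgr (ENSMUSG00000031870; chromosome 9, 8900419 to 8965425) fell by 2.41 ± 0.10 (12 ± 1.61 against 61.8 ± 5.95 CPM, adjusted p = 1.84e-07). Of 16 mammary epithelial genes, 14 fell with 0 rising, Krt8 among them (-1.11 ± 0.08, adjusted p = 2.81e-06; list median -0.96, estimated-correlation p = 0.54).

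Fatty acid synthesis genes in contralateral fat were lower in 12 of 20 cases and higher in 4 (the same over the list alone). Acly, which makes cytosolic acetyl-CoA, had the value -1.91 ± 0.10 (149 ± 22.7 against 544 ± 30 CPM, adjusted p = 4.86e-07; list median -0.58, estimated-correlation p = 0.54). Cholesterol synthesis had 7 higher and 2 lower of 20 and did not pass (median 0.12, camera adjusted p = 0.14). Fatty acid oxidation genes rose, with 12 of 16 members higher and 0 lower (Acadm 1.08 ± 0.10; list median 0.46, estimated-correlation p = 0.54). Of 28 oxidative phosphorylation genes, 13 rose and 0 fell (median 0.17, estimated-correlation p = 0.61). Lipid-associated macrophage genes rose in 13 of 15 cases and fell in 1 (Acp5 0.95 ± 0.10, estimated-correlation p = 0.54). Extracellular matrix genes rose in 13 of 27 and fell in 1 (Bgn 1.61 ± 0.09, 402 ± 16.2 against 128 ± 16.3 CPM, estimated-correlation p = 0.61). Cell cycle genes rose in 10 of 22 and fell in 0 (Cdk1 2 ± 0.23, estimated-correlation p = 0.61). Interferon response genes were lower in 13 of 23 cases and higher in 2 (Usp18 -0.82 ± 0.09, estimated-correlation p = 0.61). The macrophage list had 7 higher and 1 lower of 15 (Adgre1 0.57 ± 0.08, estimated-correlation p = 0.61), and the cytokine and chemokine list 8 higher and 2 lower of 14 (estimated-correlation p = 0.54). All 5 red blood cell genes rose (Alas2 aside, these are hemoglobin copies with near-identical sequences, whose separate counts are uncertain; list median 1.07, estimated-correlation p = 0.54). In 15 of 16 cases skeletal muscle genes were lower on HFD, with Ttn at 5.98 ± 1.31 against 1660 ± 1180 CPM in Chow contralateral fat (median -6.23, estimated-correlation p = 0.61). The B cell list had a median of -1.92 (14 of 15 below 0, 0 called, camera adjusted p = 0.31) and the T and NK cell list one of -0.97 (12 of 16 below 0, 1 called, camera adjusted p = 0.49).

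By edgeR 7847 of 15913 genes were called between the diets in contralateral fat, 3900 higher and 3947 lower, of which 466 and 1278 differed by more than 2-fold, and 14 of 27 lists passed. With offsets for gene length and GC content the split was 4799 higher and 3093 lower. With the mean of the muscle markers as a covariate, 1644 genes were called, in a design where those markers separated the diets. Of the 7847 calls 1621 were kept and 0 changed direction, and the median ratio of the fold changes with and without the covariate was 0.917.

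HFD against Chow in peritumoral fat asks how the diets differed next to the tumor. Many proliferation, macrophage, neutrophil and fat expansion genes were higher on HFD, and many fatty acid synthesis and mammary epithelial genes were lower. Of 27 lists 13 passed with a preset correlation and 0 with an estimated one. Of 23 cell cycle genes, 19 rose and 0 fell (22 and 0 when adjusted over the list alone). Among them was Mcm5, a subunit of the replicative helicase (2.02 ± 0.35, 30.5 ± 12.4 against 7.21 ± 3.09 CPM, adjusted p = 0.00384; list median 2.05, estimated-correlation p = 0.56). Macrophage genes rose in 9 of 15 cases and fell in 0 (12 and 0 over the list alone; Cd68 1.57 ± 0.23, 172 ± 27.6 against 54.8 ± 17.6 CPM, adjusted p = 0.00148, estimated-correlation p = 0.56). Lipid-associated macrophage genes rose in 12 of 15 (Lgals3 1.24 ± 0.17, Plin2 1.08 ± 0.12, estimated-correlation p = 0.42), and neutrophil genes rose in 6 of 7 with 1 falling (S100a9, an alarmin, 4.01 ± 0.67, estimated-correlation p = 0.56). Fasn (ENSMUSG00000025153; chromosome 11, 120805940 to 120824178), the fatty acid synthase, fell by 3.25 ± 0.26 (522 ± 171 against 4730 ± 904 CPM, adjusted p = 0.000134). The fatty acid synthesis list had 14 of 20 members lower and 1 higher (median -1.01, estimated-correlation p = 0.42).

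In the same comparison 8 of 20 cholesterol synthesis genes rose and 0 fell (9 and 0 over the list alone; Hmgcs1 1.17 ± 0.19, adjusted p = 0.00201, estimated-correlation p = 0.56). Adipose expansion genes rose in 8 of 9 cases, among them the Wnt antagonist Sfrp5 (ENSMUSG00000018822; 4.16 ± 0.24, 213 ± 27.1 against 11.1 ± 4.1 CPM, adjusted p = 5.99e-05, estimated-correlation p = 0.42). Cytokine and chemokine genes rose in 10 of 21 cases with 0 lower (Ccl4 3.14 ± 0.46, estimated-correlation p = 0.56). Matrix genes rose in 14 of 27 with 0 lower (Thbs1 1.25 ± 0.14, estimated-correlation p = 0.42) and interferon response genes in 9 of 23 with 0 lower (Rsad2 1.11 ± 0.22, estimated-correlation p = 0.69). Mammary epithelial genes fell in 11 of 16 cases, with the alveolar transcription factor Elf5 at -1.94 ± 0.31 (6.14 ± 2.11 against 22.4 ± 8.86 CPM, adjusted p = 0.00234, estimated-correlation p = 0.56). Immediate early and tissue handling genes had 3 higher and 0 lower of 10 (Fos 0.84 ± 0.17, adjusted p = 0.0051, estimated-correlation p = 0.56). The insulin response list did not pass (camera adjusted p = 0.2), though it held Irs1, an adaptor of the insulin receptor, at -1.51 ± 0.25 (adjusted p = 0.00282). Nor did the hypoxia and glycolysis list (5 higher and 2 lower of 18, camera adjusted p = 0.16). Red blood cell genes rose in 5 of 5 cases (median 1.54, estimated-correlation p = 0.42). Of lists that did not pass, B cell genes had a median of 1.19 (14 of 15 above 0, 0 called) and T and NK cell genes one of 0.49 (16 of 18 above 0, 0 called). Skeletal muscle genes had -2.86 (14 of 14 below 0, 0 called, camera adjusted p = 0.054) and mitochondrial genome genes -0.62 (7 of 7 below 0, 3 called, camera adjusted p = 0.072). Mitochondrial Ckmt1 fell by 1.23 ± 0.37 (adjusted p = 0.0286), a call lost without Chow peritumoral replicate 1 (-1.20), 2 (-1.22) or 3 (-1.20) or HFD peritumoral replicate 2 (-1.05) or 4 (-1.02).

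With edgeR 5353 of 15919 genes were called in peritumoral fat, 2608 higher and 2745 lower, of which 649 and 1312 differed by more than 2-fold, and 13 of 27 lists passed. The split turned to 3202 higher and 2444 lower with gene length and GC offsets, and to 5113 higher and 3686 lower with all 24 libraries in 1 fit. The count was 3102 without Chow peritumoral replicate 1, 8799 with all 24 libraries in 1 fit and 2795 without the libraries that held the lymph node marker Glycam1.

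Diet effects overlapped between the positions. Across genes, the log2 fold changes of the diet correlated at r = 0.649 between no-tumor and contralateral fat, r = 0.444 between no-tumor and peritumoral fat and r = 0.731 between contralateral and peritumoral fat. Genes are not independent replicates, so these values describe the libraries and carry no p-value. Contralateral and peritumoral fat shared 1600 higher genes (631 expected from independent lists) and 2112 lower genes (661 expected), and 33 genes were called in opposite directions (1293 expected). The labels do not say whether contralateral and peritumoral libraries share mice, so this overlap may not be an independent repeat. Malat1 stood at 10840 and 10760 CPM in Chow contralateral and peritumoral fat, against 5438 and 4972 on HFD (no-tumor fat 8420 and 7009). Total counts were at most 13.85 and 14.46 M in these Chow groups and at least 16.67 and 15.98 M on HFD. Whether such library differences add to the overlap was not tested. No-tumor and contralateral fat shared 1450 higher (531 expected) and 981 lower genes (434 expected), with 109 opposite (963 expected). No-tumor and peritumoral fat shared 805 higher (346 expected) and 621 lower genes (308 expected), with 231 opposite (658 expected). Adipose expansion genes such as Lep, Npr3 and Bmp3 rose at all 3 positions, whereas the interferon response list had a median of -0.77 in no-tumor, -0.31 in contralateral and 0.37 in peritumoral fat.

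**Figure D3:**
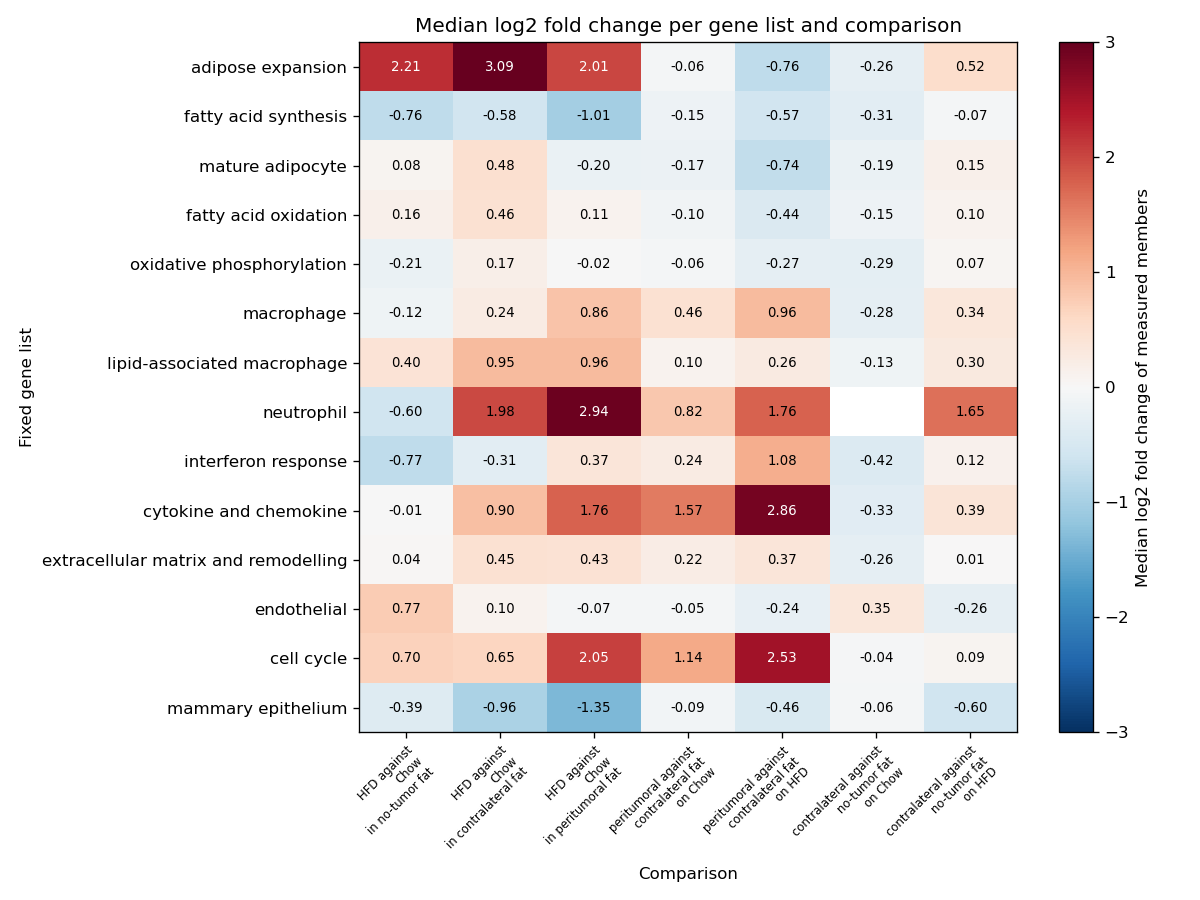
Median log2 fold change over the measured members of the gene lists named at the left in the 7 comparisons of 2 groups, with red for higher and blue for lower values on a scale from -3 to 3. The blank square is a list with fewer than 3 measured members. The adipose expansion list has medians of 2.21, 3.09 and 2.01 in the 3 diet comparisons, and the cell cycle list has its highest median, 2.53, between peritumoral and contralateral fat on HFD.

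Peritumoral against contralateral fat on Chow asks how fat near the tumor differed in lean mice. No single gene passed with edgeR (0 of 16057, against 1381 at an unadjusted p under 0.05), while several gene groups lay on 1 side. All 22 cell cycle genes had positive values (median 1.14, camera adjusted p = 4.3e-11, estimated-correlation p = 0.36). So did all 23 interferon response genes (median 0.24, camera adjusted p = 6.8e-11, estimated-correlation p = 0.35) and 14 of 15 macrophage genes (median 0.46, camera adjusted p = 5.4e-09, estimated-correlation p = 0.35). Adjusted over the list alone, 5 macrophage, 5 interferon response, 3 cytokine and 0 cell cycle genes passed, all higher. The proliferation marker Mki67 stood at 24.2, 29.6, 56.8 and 89.0 CPM in the 4 peritumoral libraries, against a range of 13.8 to 27.2 CPM in the contralateral ones.

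Fat cell genes lay on the lower side on Chow, with 15 of 17 mature adipocyte genes (median -0.17, estimated-correlation p = 0.35) and 19 of 20 fatty acid synthesis genes (median -0.15, estimated-correlation p = 0.35) below 0. Skeletal muscle genes were below 0 in 17 of 18 cases (median -1.57, estimated-correlation p = 0.50), where 3 of the 4 contralateral libraries held Ckm at 88.8 to 210 CPM. B cell genes were below 0 in 14 of 15 cases (median -0.85, camera adjusted p = 0.52) and T and NK cell genes in 13 of 16 (median -0.52, camera adjusted p = 0.84). Of 28 lists, 14 passed with a preset correlation, 0 with an estimated correlation (adjusted p from 0.35 to 0.65) and 0 with fry. DESeq2 called 19 genes (on simulated counts of this comparison 25 of its 135 calls were false, and 6 of 104 with edgeR), limma voom 0, and edgeR 3 with no low-count filter and 1 without Chow contralateral replicate 1.

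Peritumoral against contralateral fat on HFD asks the same question in obese mice. Many proliferation, macrophage, neutrophil, interferon and chemokine genes were higher next to the tumor, and many adipocyte, insulin response and fatty acid oxidation genes were lower. Of 28 lists 14 passed with a preset correlation and 0 with an estimated one. All 23 cell cycle genes rose (median 2.53). Kif11, a spindle motor, rose by 2.59 ± 0.31 (29.7 ± 11.2 against 4.89 ± 1.57 CPM, adjusted p = 0.00108), and Mki67 rose by 2.03 ± 0.25 (141 ± 36.5 against 34.2 ± 12.1 CPM, adjusted p = 0.00121, estimated-correlation p = 0.53). Macrophage genes rose in 13 of 15 cases and fell in 0 (14 and 0 when adjusted over the list alone, median 0.96). They held the Fc receptor Fcgr1 (ENSMUSG00000015947, 2.73 ± 0.19, 42.8 ± 10.3 against 6.37 ± 1 CPM, adjusted p = 0.000158) and the mannose receptor Mrc1 (1.39 ± 0.17, 729 ± 176 against 276 ± 30.2 CPM, adjusted p = 0.00109, estimated-correlation p = 0.53). Interferon response genes rose in 21 of 23 cases and fell in 0 (22 and 0 over the list alone). The nucleic acid sensor Zbp1 rose by 2.03 ± 0.15 (46.8 ± 10 against 11.4 ± 0.697 CPM, adjusted p = 0.000158; list median 1.08, estimated-correlation p = 0.53).

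Cytokine and chemokine genes rose in 19 of 21 cases (median 2.86), with the monocyte attractants Ccl7 (2.86 ± 0.19, 42.3 ± 10 against 5.80 ± 1.03 CPM, adjusted p = 0.000158) and Ccl2 (3.41 ± 0.31, adjusted p = 0.000296, estimated-correlation p = 0.53). Neutrophil genes rose in 5 of 7 cases and fell in 0 (6 over the list alone; Csf3r 1.98 ± 0.22, estimated-correlation p = 0.53). Matrix genes rose in 10 of 27 cases and fell in 1. They held the collagen Col12a1 (ENSMUSG00000032332; 2.19 ± 0.15, 221 ± 46.3 against 48.2 ± 3.21 CPM, adjusted p = 0.000158) and the protease inhibitor Timp1 (3.95 ± 0.33, estimated-correlation p = 0.53). The adhesion molecule Chl1 (ENSMUSG00000030077; chromosome 6, 103510876 to 103733035) had the lowest adjusted p of the comparison, at 4.41 ± 0.22 (34.4 ± 7.25 against 1.60 ± 0.439 CPM, adjusted p = 4.01e-05). Lymphocyte lists were higher in sign. Of 17 T and NK cell genes 16 were above 0 (4 called over all genes and 0 adjusted over the list alone; median 1.01, estimated-correlation p = 0.78). The B cell list had a median of 2.07 (1 of 14 called, camera adjusted p = 0.1), and the lymph node stroma and high endothelium list had 1.43 (1 of 3 called, camera adjusted p = 0.3). The lymph node marker Glycam1 stood at 19 CPM in HFD peritumoral replicate 2, 5.25 in replicate 4 and 7.58 in HFD contralateral replicate 1, and the B cell gene Ms4a1 at 22.9, 8.43 and 3.09 CPM in the same libraries.

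On the lower side, mature adipocyte genes fell in 13 of 17 cases with 0 rising (15 over the list alone; Plin1, the lipid droplet coat protein, -0.95 ± 0.20, 419 ± 133 against 803 ± 69.1 CPM, adjusted p = 0.00904; list median -0.74, estimated-correlation p = 0.55). Insulin response genes fell in 9 of 10 cases (median -0.59, estimated-correlation p = 0.55). Fatty acid oxidation genes fell in 11 of 16 (Acadvl -0.59 ± 0.11, adjusted p = 0.00663, estimated-correlation p = 0.58), and fatty acid synthesis genes fell in 9 of 20 (Mlxipl -0.81 ± 0.19, adjusted p = 0.0132, estimated-correlation p = 0.56). Oxidative phosphorylation genes fell in 10 of 28, and in 21 of 28 with gene length and GC offsets (Sdha -0.48 ± 0.11, adjusted p = 0.0127, estimated-correlation p = 0.58), and 0 genes of these 4 lists rose. Thermogenic fat genes fell in 5 of 10 cases and rose in 2 (Prdm16 -0.75 ± 0.15, adjusted p = 0.00784, estimated-correlation p = 0.58). Endothelial markers had a median of -0.24 with 0 of 14 called, and mammary epithelial markers a median of -0.46 with 0 of 16 called (camera adjusted p = 0.02, estimated-correlation p = 0.78).

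Of 15627 genes tested, edgeR called 4610, 2631 higher and 1979 lower, of which 892 and 130 differed by more than 2-fold, and 14 of 28 lists passed. With gene length and GC offsets the split turned to 2389 higher and 2548 lower. The count was 2783 with the B cell mean as a covariate, 968 without the Glycam1 libraries (2 peritumoral against 3 contralateral; 798 higher and 170 lower), and 3034, 2960, 2750 and 2866 without HFD contralateral replicate 1, 2 or 3 or HFD peritumoral replicate 4.

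Whether the tumor-side effect differed between the diets was tested as an interaction. Interferon response genes had larger values on HFD, with all 23 members above 0 (median 0.84, camera adjusted p = 2.6e-14, estimated-correlation p = 0.49, fry adjusted p = 0.041) and 18 passing when adjusted over the list alone. Oasl2 (1.16 ± 0.18) and Zbp1 (1.36 ± 0.23) each had an adjusted p of 0.0521 over all genes. Cell cycle genes had a median of 1.46 (5 of 23 passing over the list alone, estimated-correlation p = 0.49). Mature adipocyte genes had -0.53 (5 of 17 lower over the list alone, estimated-correlation p = 0.49) and insulin response genes -0.45 (3 of 10 lower over the list alone, estimated-correlation p = 0.49). Markers of other tissues had larger medians in the same interaction, with 0 genes called: skeletal muscle 3.83 (18 of 18 above 0, camera adjusted p = 0.00047, estimated-correlation p = 0.61), B cell 3.02 (14 of 15 above 0, camera adjusted p = 0.074), lymph node stroma and high endothelium 2.13 (3 of 4 above 0, camera adjusted p = 0.32) and T and NK cell 1.74 (17 of 18 above 0, camera adjusted p = 0.046, estimated-correlation p = 0.66). Mitochondrial genome genes had -0.49 (7 of 8 below 0, camera adjusted p = 0.0059, estimated-correlation p = 0.51). No gene of 16859 passed with edgeR (0, against 3349 at an unadjusted p under 0.05). Of 28 lists 15 passed with a preset correlation and 0 with an estimated one. DESeq2 called 727 genes and limma voom 1472. The edgeR count was 333 with all 24 libraries in 1 fit and 7 with no low-count filter. It was 1911 when HFD peritumoral replicate 1 was left out, 68 without Chow peritumoral replicate 3, and 1 without Chow contralateral replicate 4. With the replicate number as a block it was 43 (41 higher and 2 lower), and the labels do not say whether same-numbered samples share a mouse. Across genes the side effects on the 2 diets correlated at r = 0.514, with genes that are not independent replicates. Signs matched for 3787 of the 4451 genes called on HFD and tested on Chow (85.1%), with a slope of 0.325 of Chow on HFD.

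Contralateral against no-tumor fat on Chow asks what a tumor elsewhere in the animal went along with in lean mice. Some endothelial genes were higher in contralateral fat and some oxidative phosphorylation genes were lower, and neither list passed with an estimated correlation. Among single genes outside these groups, Prx, a myelin protein, rose by 1.21 ± 0.17 (11.4 ± 1.45 against 4.95 ± 1.26 CPM, adjusted p = 0.00524). The potassium channel Kcna1 rose by 1.37 ± 0.12 (26.1 ± 2.51 against 10.2 ± 1.81 CPM, adjusted p = 0.000745) and the nuclear noncoding RNA Neat1 by 1.15 ± 0.12 (904 ± 156 against 411 ± 34 CPM, adjusted p = 0.00166). Of 14 endothelial markers, 8 rose and 0 fell (11 and 0 when adjusted over the list alone; 2 and 0 with gene length and GC offsets). They held Esam at 0.51 ± 0.09 (adjusted p = 0.0119) and Tie1 at 0.47 ± 0.07 (adjusted p = 0.00747), both of which missed the threshold with all 24 libraries in 1 fit (list median 0.35, estimated-correlation p = 0.61). Of 28 oxidative phosphorylation genes, all had negative values, 5 fell and 0 rose (17 and 0 over the list alone), with Ndufa1 at -0.52 ± 0.09 (adjusted p = 0.00998; list median -0.29, estimated-correlation p = 0.71).

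In the same contrast cholesterol synthesis genes were below 0 in 19 of 20 cases and 2 fell (median -0.36, estimated-correlation p = 0.61). The mitochondrial genome list had 2 of 7 lower and a median of -0.32 (estimated-correlation p = 0.71), in libraries whose mitochondrial ribosomal RNA share was 24.87% ± 1.4 against 32.42% ± 2.38 (SD). Skeletal muscle genes were above 0 in 18 of 18 cases with 0 called (median 2.48; Ttn 1660 ± 1180 against 142 ± 229 CPM, estimated-correlation p = 0.71). Of 14 B cell genes, 14 were above 0 with 0 called (median 2.23, estimated-correlation p = 0.76), with Glycam1 at 72.9 CPM in Chow contralateral replicate 4. T and NK cell genes were above 0 in 10 of 12 cases with 1 called (median 1, camera adjusted p = 0.18). By edgeR 1268 of 15946 genes were called, 786 higher and 482 lower, of which 116 and 4 differed by more than 2-fold. Of 26 lists 11 passed, 0 of them with an estimated correlation. With gene length and GC offsets the split turned to 430 higher and 842 lower. The 4 contralateral libraries lay above the 4 no-tumor libraries in Malat1 (exact permutation p = 0.0286, adjusted p = 0.04) and below them in total counts (exact permutation p = 0.0286, adjusted p = 0.05). The number of called genes was 692 with all 24 libraries in 1 fit, 386 with the B cell mean and 125 with the muscle mean as a covariate, and 426 without the library with Glycam1. It was 383, 750, 573 and 426 without Chow contralateral replicates 1 to 4, and 672, 1986, 375 and 564 without Chow no-tumor replicates 1 to 4.

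Contralateral against no-tumor fat on HFD asks the same in obese mice. Neutrophil and some macrophage genes were higher in contralateral fat, and some mammary epithelial genes were lower. Of 27 lists 15 passed with a preset correlation and 0 with an estimated one. Hdc (ENSMUSG00000027360), the histamine-forming enzyme, rose by 1.36 ± 0.13 (7.16 ± 0.404 against 2.77 ± 0.403 CPM, adjusted p = 0.00112). All 4 measured neutrophil genes rose (median 1.65, Mmp9 1.03 ± 0.12, adjusted p = 0.00163, and S100a9 4.17 ± 0.52, 5.44 ± 2.6 against 0.297 ± 0.217 CPM, adjusted p = 0.00388, estimated-correlation p = 0.06). Prom1, a membrane protein of epithelial progenitors, fell by 1.31 ± 0.20 (adjusted p = 0.00604). Mammary epithelial genes fell in 7 of 16 cases with 0 rising (11 over the list alone; Krt8 -0.76 ± 0.09, adjusted p = 0.00163, estimated-correlation p = 0.13). Macrophage genes rose in 6 of 15 cases with 0 falling (12 over the list alone; C1qb 0.59 ± 0.09, adjusted p = 0.00697, estimated-correlation p = 0.27). Mature adipocyte genes rose in 5 of 17 (7 over the list alone; Pnpla2 0.42 ± 0.06, adjusted p = 0.00437, estimated-correlation p = 0.13). Krt8, C1qb and Pnpla2 missed the threshold with all 24 libraries in 1 fit.

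Of 14 endothelial markers on HFD, 13 were below 0 and 1 fell (median -0.26, estimated-correlation p = 0.55). The hypoxia and glycolysis list had 1 of 16 members higher, and 5 higher and 1 lower over the list alone (median 0.14, camera adjusted p = 0.026, estimated-correlation p = 0.25). By edgeR 956 of 15718 genes were called, 427 higher and 529 lower (16 and 87 by more than 2-fold), and 15 of 27 lists passed; with gene length and GC offsets the split was 654 higher and 385 lower. Here the 4 contralateral libraries lay below the 4 no-tumor libraries in Malat1 (exact permutation p = 0.0286, adjusted p = 0.04) and above them in total counts (exact permutation p = 0.0286, adjusted p = 0.05). The number of called genes was 238 with all 24 libraries in 1 fit, and 531 without HFD contralateral replicate 3 and 560, 461 and 365 without HFD no-tumor replicates 1 to 3.

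Contralateral and no-tumor fat differed in a diet-dependent way when that was tested as an interaction. Values were lower on HFD than on Chow for Kcna1 (-2.06 ± 0.19, adjusted p = 9.96e-06) and Neat1 (-1.53 ± 0.16, adjusted p = 4.95e-05). All 14 endothelial markers were below 0, 11 of them called (the same over the list alone; with gene length and GC offsets 5 called and 1 of 14 above 0; median -0.65; Kdr, a receptor of vascular growth factor, -0.89 ± 0.17, adjusted p = 0.00303, estimated-correlation p = 0.45). Oxidative phosphorylation genes went the other way, with 28 of 28 above 0 and 15 called (21 over the list alone; median 0.38; Cox4i1 0.56 ± 0.10, adjusted p = 0.00202, estimated-correlation p = 0.45). So did mature adipocyte genes with 8 of 17 called (9 over the list alone; Adipoq 0.63 ± 0.12, adjusted p = 0.00248, estimated-correlation p = 0.45), and macrophage genes with 8 of 15 called (11 higher and 1 lower over the list alone; Adgre1 0.66 ± 0.14, adjusted p = 0.00444, estimated-correlation p = 0.47). Neutrophil gene Mmp9 had an interaction of 1.40 ± 0.18 (adjusted p = 0.000261) and Ckmt1 of -1.87 ± 0.45 (adjusted p = 0.00898). Mitochondrial genome genes were above 0 in 8 of 8 cases with 3 called (median 0.44, estimated-correlation p = 0.45). Library measures reversed between the diets as well. Contralateral against no-tumor Malat1 was 10840 against 8420 CPM on Chow and 5438 against 7009 on HFD. The mitochondrial ribosomal RNA share was 24.87% against 32.42% and 23.85% against 21.61%, and total counts reversed too. A difference between libraries and a diet-dependent effect of the tumor cannot be told apart here. Markers of other tissues were below 0 with 0 called: skeletal muscle genes in 18 of 18 cases (median -2.63, camera adjusted p = 0.00051, estimated-correlation p = 0.47), B cell genes in 15 of 15 (median -1.75, camera adjusted p = 0.15) and T and NK cell genes in 16 of 16 (median -1, camera adjusted p = 0.21).

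By edgeR 3314 of 16676 genes had an interaction of diet and tumor bearing, 1657 on each side (55 higher and 662 lower by more than 2-fold), and 18 of 28 lists passed, 0 of them with an estimated correlation. With gene length and GC offsets the split was 2939 higher and 1172 lower. The count was 1556 with all 24 libraries in 1 fit, 1775 with the muscle mean as a covariate and 2059 without the Glycam1 libraries. Across genes, the contralateral effects on the 2 diets correlated at r = -0.25, a comparison chosen after the data were seen; 5 genes were higher on both diets (21 expected) and 117 were called in opposite directions (39 expected).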

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

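The tests of lymph node and muscle RNA named in this part were chosen after the results were seen. In groups of 4 libraries, a library was picked out where its gap to the nearest other took up nearly the whole range of its group. This happened in 24 of 102 groups. About 1 in 20, or 5.1, would be expected for independent, normally distributed values. CPM are skewed, and measures such as Ckm and Ckmt2 or Glycam1 and Ms4a1 rise together. A count of 1 against 0 in the rest of a group always meets the rule. The excess over 5.1 therefore does not show outliers beyond chance.

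Lymph node and B cell genes picked out Chow contralateral replicate 4, with Glycam1 at 72.9 CPM (nearest 0.34) and Ms4a1 at 20.6 CPM (nearest 2.32), and HFD contralateral replicate 1, with Glycam1 at 7.58 CPM (nearest 1.18). Muscle genes picked out Chow no-tumor replicate 3, with Acta1 at 127 CPM (nearest 16.3) and Ckm at 54.1 CPM (nearest 5.49). They picked out Chow peritumoral replicate 2, with Ckm at 104 CPM (nearest 11.8) and Ckmt2 at 2.37 CPM (nearest 0.601), and HFD peritumoral replicate 2, with Ckm at 10.8 CPM (nearest 0.244) and Ckmt2 at 0.821 CPM (nearest 0). Chow contralateral replicate 3 had less of it than the others, with Ckmt2 at 0.068 CPM (nearest 1.69). Near the floor, Ckm stood at 0.0619 CPM in HFD contralateral replicate 2 and 0.0649 CPM in HFD no-tumor replicate 2, with the other libraries of each group at 0.

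Creatine, fat and proliferation genes picked out single libraries too. Gamt stood at 10.5 CPM in Chow no-tumor replicate 2 (nearest 6.06) and 6.88 CPM in HFD peritumoral replicate 3 (nearest 9.5), Ckmt1 at 1.25 CPM in HFD no-tumor replicate 4 (nearest 2.8), and Lep at 372 CPM in Chow contralateral replicate 3 (nearest 213). Mki67 stood at 32.8 CPM in Chow no-tumor replicate 1 (nearest 22.7) and 52.3 CPM in HFD contralateral replicate 2 (nearest 28.7).

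Library measures picked out Chow contralateral replicate 2, with 11.69 M counts (nearest 13.64) of which 11.367% came from the gene Gm42418 (nearest 0.9%), so that 1 gene took a large share of its counts. Gm42418 also stood out at 0.036% in HFD contralateral replicate 2 (nearest 0.023%) and 0.041% in HFD no-tumor replicate 4 (nearest 0.022%). The mitochondrial ribosomal RNA share was 20.541% in HFD no-tumor replicate 1 (nearest 21.903%), and Malat1 stood at 7730 CPM in Chow no-tumor replicate 1 (nearest 8580).

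The interaction of diet and tumor bearing was picked out because a test of the difference itself called 3314 genes with edgeR, Kcna1 among them (-2.06 ± 0.19).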

How the results depend on the processing

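The muscle covariate, the gene length and GC offsets and the fits without Glycam1 libraries were chosen after the results were seen; the other alternatives were chosen before the data were examined. With the gene length and GC offsets 16 of the 7847 calls for diet in contralateral fat, 1 of the 5353 in peritumoral fat and 2 of the 3314 for the interaction with bearing turned their direction. No call turned its direction under the other alternatives. The larger side of the diet calls did turn, from lower to higher, with DESeq2 (3736 of 7416 in contralateral and 3001 of 5890 in peritumoral fat), with all 24 libraries in 1 fit (3933 of 7498 and 5113 of 8799) and with no low-count filter, in peritumoral fat with voom, and in each of these 2 comparisons when either of 2 single libraries was left out.

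DESeq2 called 19 genes between peritumoral and contralateral fat on Chow (edgeR 0, voom 0) and 727 for the interaction of diet and tumor side (edgeR 0), voom called 1472 for that interaction, and edgeR with no low-count filter called 3 and 7. With all 24 libraries in 1 fit the counts were 8799 for diet in peritumoral fat, 692 and 238 for tumor bearing on Chow and HFD, 333 for the interaction with side and 1556 for the interaction with bearing. With the B cell mean as a covariate they were 2783 for tumor side on HFD and 386 for tumor bearing on Chow. With the muscle mean they were 1644 for diet in contralateral fat, 125 for tumor bearing on Chow and 1775 for the interaction with bearing. Without the libraries with Glycam1 they were 2795 for diet in peritumoral fat, 968 for tumor side on HFD, 426 for tumor bearing on Chow and 2059 for the interaction with bearing; the cause was not tested, and fewer libraries alone lower a count. This last setting did not apply to diet in no-tumor fat. RLE factors, the stricter filter and gene length and GC offsets moved none of the 9 counts by over 1.5 times.

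Leaving out 1 library gave 3102 (without Chow peritumoral replicate 1) to 6003 genes for diet in peritumoral fat, 2990 to 4592 in no-tumor and 7084 to 7555 in contralateral fat. For tumor side it gave 0 to 1 genes on Chow (1 without Chow contralateral replicate 1) and 2750 (without HFD contralateral replicate 3) to 6425 on HFD. For tumor bearing it gave 375 (without Chow no-tumor replicate 3) to 1986 (without Chow no-tumor replicate 2) on Chow and 365 (without HFD no-tumor replicate 3) to 1220 on HFD. The interactions gave 0 to 1911 with side (1911 without HFD peritumoral replicate 1) and 2435 to 3753 with bearing.

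With the replicate number as a block the counts were 356 and 629 for tumor bearing on Chow and HFD and 43 for the interaction with side, and the other 6 counts stayed within 1.5 times. Of the named genes 33 lost and 18 gained a call with the block, and of the lists 7 gained one. The labels do not say whether samples of the 2 sides with the same number share a mouse. In no comparison were all 4 same-numbered correlations over 0.1, and at most 2 of 4 libraries correlated best with their own number. Between the sides the correlations were -0.11, 0.107, 0.196 and 0.322 on HFD and lay between -0.074 and 0.245 on Chow, so a shared mouse was left open.

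Of the gene list results, 123 of those that passed missed the threshold with an estimated correlation, and 67 with fry, where 4 were gained. With an estimated correlation 1 list still passed, endothelial markers for diet in no-tumor fat, and 0 passed in each other comparison. Leaving out 1 library lost 97 list calls and gained 82, while 2143 list results were kept and 94 changed in another way. Of the named genes, DESeq2 gained 56 calls and lost 0, 1 fit of all 24 libraries lost 95 and gained 10, and leaving out 1 library lost 419 and gained 103 while 5804 stayed on the same side. All 5 correlations across genes moved little with a minimum of 5 CPM, to r = 0.729, 0.463 and 0.722 between the diet effects, 0.58 between the side effects and -0.22 between the bearing effects.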

Other observations

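Chosen after the results were seen were the tests of gene length and GC content, muscle RNA, lymph node RNA, adipocyte share, tumor cells, clock genes and myelin genes.

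Clock genes were set beside the diet effects, since a different time of collection would move the Dbp and Arntl groups apart. Between the diets the medians of the Dbp and Arntl groups were 0.12 and -1.05 in no-tumor fat and -0.17 and -0.71 in contralateral fat. They were -0.57 and -0.04 in peritumoral fat, and 0 of these 3 comparisons met the rule for opposite movement. In no-tumor fat 5 of 10 Dbp group genes were called higher and 1 lower, and 3 of 4 Arntl group genes were called lower with 0 higher. A different time of collection therefore stays open there. Next to the tumor, against contralateral fat, the medians were -0.65 and 0.58 on HFD and -0.19 and 0.42 on Chow, so a shift in these 2 comparisons stays open. Between contralateral and no-tumor fat the medians of the 2 groups were 0.19 and -0.25 on Chow and -0.16 and 0.08 on HFD. In the interaction of diet and tumor bearing they were -0.28 (8 of 10 below 0) and 0.35 (4 of 4 above 0). A different time of collection stays open for tumor bearing too.

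Some myelin genes differed between contralateral and no-tumor fat, with 7 of 14 called higher on Chow (median 0.75) and 3 of 14 called lower on HFD (median -0.48). The list was put together because genes such as Prx had been called in these libraries, so its p-values, the larger of which was 3e-05, restate that finding and decide nothing. Between the diets, 10 of 14 myelin genes were called lower on HFD in contralateral fat and 1 higher (median -1.16). In peritumoral fat 9 were lower and 0 higher (median -1.51), and in no-tumor fat 1 was lower and 2 higher (median 0.16). The amount of peripheral nerve in each dissected piece and a change of gene activity in nerve cannot be told apart here, and both stay open.

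Other splits of the same libraries were counted for each number of called genes. For diet, 1 of 35 splits, the real one, gave as many genes (3943, 7847 and 5353, highest other 0 at each position). The same held for tumor side on HFD (4610, highest other 0). It held too for tumor bearing on Chow (1268, highest other 76) and on HFD (956, highest other 2). For these 6 counts 1 of 35 is the lowest share the test can give, which makes chance less likely but cannot exclude it. Nor can the splits tell diet or position from anything else that differed between the groups. For tumor side on Chow all 35 splits gave at least the 0 genes called with edgeR (1381 at an unadjusted p under 0.05, DESeq2 19, voom 0). The highest other gave 70, from a split that set Chow contralateral replicates 1, 2 and 4 and Chow peritumoral replicate 2 against the rest. Those were the libraries with the most muscle RNA, though Chow peritumoral replicate 3 also held some (Ckm at 11.8 CPM). The highest other split for tumor bearing on Chow likewise joined Chow contralateral replicates 1, 2 and 4 with no-tumor replicate 3. For the interaction with bearing 1 of 100 splits gave 3314 genes (highest other 1114). For the interaction with side all 100 gave at least the 0 called with edgeR (3349 at an unadjusted p under 0.05, DESeq2 727, voom 1472), and the highest, 4412, came from exchanging the Chow contralateral and peritumoral libraries wholly, which adds the 2 side effects up.

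Genes such as Kcna1 and Neat1 differed between contralateral and no-tumor fat on Chow, in a count of 1268 that many settings lowered. With gene length and GC offsets 66% of them (837) were still called in the same direction, which argues against such a trend as the whole cause, while the split turned to 430 higher and 842 lower. With the muscle mean as a covariate the median ratio of log2 fold changes over the called genes was 0.997 (quartiles 0.91 and 1.09). Their folds thus did not depend on the muscle mean. Calling favors genes that are steady within a group, whereas Ckm ran from 0.749 to 210 CPM in Chow contralateral and from 0 to 54.1 CPM in Chow no-tumor libraries. The ratio is therefore weak evidence on muscle RNA. The fit with the covariate called 125 genes, because the median SE grew from 0.088 to 0.111 at a median absolute log2 fold change of 0.41 before and after. The tumor elsewhere in the animal stays open as an untested cause, as do differences between the pieces dissected and in the time of collection. The count without single libraries ran from 375 without Chow no-tumor replicate 3 to 1986 without Chow no-tumor replicate 2.

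Cell cycle, macrophage and interferon response genes were higher in peritumoral than contralateral fat on HFD, with a median of 1.65 over 61 members. Without the libraries with Glycam1, which left 2 peritumoral and 3 contralateral libraries, the median was 1.26 (quartiles of the ratio 0.76 and 0.87), which argues against lymph node RNA as the whole source though it may hold a part. A smaller share of adipocyte RNA would raise macrophage and endothelial genes alike, and their medians lay 1.2 apart (0.96 and -0.24). Tumor cells in the dissected fat cannot be told apart from a response of the fat: mammary epithelial markers had a median of -0.46, but the tumor need not express them.

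Gatm was higher next to the tumor on HFD by 1.80 ± 0.30, with 4 of 4 peritumoral libraries above the contralateral ones. Without the libraries with Glycam1 it was 1.24 ± 0.28 (adjusted p = 0.0455), between the full value and 0.90, the bound set for the test. Chow contralateral replicate 4, with Glycam1 at 72.9 CPM, held Gatm at 8.56 CPM, and HFD contralateral replicate 1, with Glycam1 at 7.58, at 8.55 CPM. HFD peritumoral replicates 1 and 3, with Glycam1 at 0.056 and 0 CPM, held 12.5 and 24.8 CPM of Gatm. Replicates 2 and 4, with Glycam1 at 19 and 5.25 CPM, held 38.0 and 37.7. These values argue against lymph node RNA as the whole source, and a part stays open. With the macrophage mean as a covariate it was 1.30 ± 1.18 (adjusted p = 0.759): the call ended because the SE grew, as the covariate separates the groups, and macrophages may hold the transcript. Whether fat cells, immune cells or tumor cells carry it stays open in bulk tissue.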
